A study of Homo sapiens with 9 samples.

How the data were processed

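Gene expression was measured in 9 samples of the human lymphoma cell line U937: control cells kept at 37 °C, and cells heated for 15 min at 42 or 44 °C and then kept at 37 °C for 0, 1, 3 or 6 h. Groups were taken from the sample labels. Per the labels' protocols, total RNA was purified on RNeasy columns and freed of DNA with DNase, cDNA was made from it in a one-cycle 3′ amplification, and biotin-labelled cRNA transcribed from the cDNA was hybridised to Human Genome U133 Plus 2.0 arrays. The deposited values were linear intensity values, 1 per probe set and array, for 54675 probe sets. Per the submitters' processing notes they are MAS5 signals. The scaling target was not given in the sources used here. The 2% trimmed means of the arrays ran from 101 to 211, so the arrays had not been brought to a common level. Scanner files were not analysed here.

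Each array was multiplied by 1 factor (0.474 to 0.989) to give a trimmed mean of 100 over the 54613 probe sets that are not controls, with 2% trimmed at each end. Such scaling keeps any difference between arrays in the shape of the signal distribution, which can shift bright genes as a group. Values under the median of all scaled values (12.5) were raised to it, and log2 was taken. The floor limits folds of dim genes, and a fold with the floor on 1 side is a bound. Of all 54675 probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 had several and 11777 were not listed there. The 62 controls are counted among these and were left out of all gene values. Probe sets with several symbols or none were not named. Of those with 1 symbol, 41043 matched an entry of the RefSeq gene table by gene number and 0 symbols had to be updated. That table served for names alone. For each gene the probe set with the highest mean log2 signal over the 9 arrays was used. This gave 19775 genes, of which 14544 were above the floor on 1 or more arrays and 9913 on all, and 10523 had 2 or more probe sets.

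The 12 comparisons were each heated array against the control (8) and 44 °C against 42 °C at each recovery time (4). With 1 array per group no test was run, and a gene was counted as higher or lower when its log2 fold was at least 1 in size. The spread between arrays was described from differences among the control and the 2 arrays at 0 h in 10 bins of mean signal. It includes any early response to heat. Those arrays had trimmed means of 160 to 172, where later arrays ran from 101 to 211. The spread may therefore be too low for comparisons of later arrays. Simulated arrays took their spread from the robust SD per bin of the difference between the 44 °C array at 0 h and the control, so any heat response in it counts as spread there. In data simulated for the comparison of 44 °C at 0 h with the control over 19775 genes, the size rule recovered 27 of 50 genes changed 2-fold, 48 of 50 changed 3-fold, 50 of 50 changed 4-fold and 47 of 50 changed 8-fold, and it called 519.0 of 19575.0 unchanged genes (2.65%). The other 11 comparisons were simulated without changed genes, from the level of their second array and the same spread, and 466 to 536 genes were called over all 12. For the overlap of both temperatures, 100 simulations of unchanged arrays against 1 shared control were drawn, and 100 with a baseline array for each temperature. The simulations for the overlap took their spread from gene values after the floor, the others from probe sets before it. In the others, the floor and the probe set of each gene came from the simulated pair alone, not from all arrays.

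For 32 gene lists the median log2 fold, the members that rose or fell and the percentile of the median among 10000 random lists of the same size, matched on mean signal in 10 bins, were computed. The lists were heat shock chaperones, heat shock factors, chaperonin TRiC, the unfolded protein response, the integrated stress response, NRF2 targets, metallothioneins, immediate early genes, inflammatory NF-kB targets, interferon response, proapoptotic and antiapoptotic genes, p53 targets, growth arrest, S phase, mitosis (G2/M), cholesterol synthesis, proteasome, ribosomal proteins, tRNA synthetases, oxidative phosphorylation, SR proteins with CLK kinases, histones, zinc fingers, solute carriers, small nucleolar RNA hosts, housekeeping genes, and markers of monocytes, T cells, B cells, epithelium with fibroblasts, and erythroid cells. Named genes were, in each comparison, the 10 largest rises and 10 largest falls among genes past the size rule in which no other probe set off the floor had the opposite sign by 0.5 or more, up to 4 members of each list past the rule, and 22 stress and apoptosis genes named whatever their values. Names made only of clone or frame labels, and histone and immunoglobulin genes, were left out of the largest changes. From 50 to 79 genes were named per comparison.

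The scaling, the floor, the probe set rule, the size rule, the lists and the alternatives were chosen before the data were examined, except for 1 alternative floor. The alternatives were quantile normalisation, a floor at the 25th (2.91), 65th (34.1) or 80th (124) percentile of scaled values, the median over all probe sets of a gene, the 0 h array of the same temperature as baseline, and a threshold at the 99th percentile of the early differences per bin. The 80th percentile was added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.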

Results

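U937, a human lymphoma cell line that grows in suspension and has features of monocytes, was heated for 15 min at 42 or 44 °C and then kept at 37 °C for 0, 1, 3 or 6 h. Total RNA of each heated culture and of unheated control cells was hybridised to an Affymetrix array that measures transcripts through short probes near their 3′ ends. There were 9 arrays, 8 from heated cells and 1 from control cells, with 1 array per condition. The series title places the study in the gene profile of apoptosis induced by heat stress. Each heated array was set against the control array to show the response to heat, and the 44 °C array was set against the 42 °C array of the same recovery time to show the effect of temperature. The 1 control array has no time in its label and stands for every recovery time. Changes at 1, 3 and 6 h therefore cannot be told apart from time in culture or handling, also where both temperatures share them.

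The deposited signals had a median of 12.7 to 27.2 per array and a trimmed mean of 101 to 211, and all arrays were scaled to a common trimmed mean. After scaling, 48.3 to 52.6% of probe sets per array lay above a floor signal of 12.5. The ratio of 3′ to 5′ signals, a sign of RNA integrity, ran from 1.18 to 1.36 for ACTB and from 0.939 to 1.13 for GAPDH. The number of arrays limits the precision of every value. No condition had a replicate, so no test was run, no p-value is given and all values describe these arrays. Among 19775 genes, those that differed by 2-fold or more are said to have risen or fallen, and folds that use the floor are bounds. Between the control array and the pair of 0 h arrays, the 99th percentile of the size of log2 differences was 1.10 for the brightest of 10 bins of genes and 1.67 for genes with a mean signal near 39.2, so a 2-fold change lies inside that range, which also holds the early response to heat. Of 642 calls of named genes over the 12 comparisons, 432 stayed past 2-fold with a floor of 34.1, and 621 with quantile normalisation. In data simulated without change, 466 to 536 genes per comparison passed 2-fold and 11 to 24 passed 4-fold. Their spread was taken from the difference of the 44 °C array at 0 h from the control with any heat response in it. For that pair itself 519 unchanged genes were called in simulated data, while 373 genes differed between the arrays. Each simulated pair also had its floor and probe sets chosen from that pair alone, where the real data used all arrays. Simulated numbers may therefore be too high. They may also be too low for arrays that differed more in level than the control and 44 °C 0 h arrays, with trimmed means of 165 and 172. A number found below them does not show that nothing changed, and one above them may reflect such differences. Medians of gene lists are in log2. Their percentiles are among 10000 random lists of the same size, matched on mean signal in 10 bins. Such matching is coarse for bright genes. For 44 °C against 42 °C at 3 h the 1978 brightest genes had a median of -0.10. The 20 genes nearest in signal to each ribosomal protein gene had a median of -0.71 there. Percentiles of lists with bright members, heat shock chaperones among them, therefore do not control for a shift that differs with brightness within a bin.

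**Figure D1:**
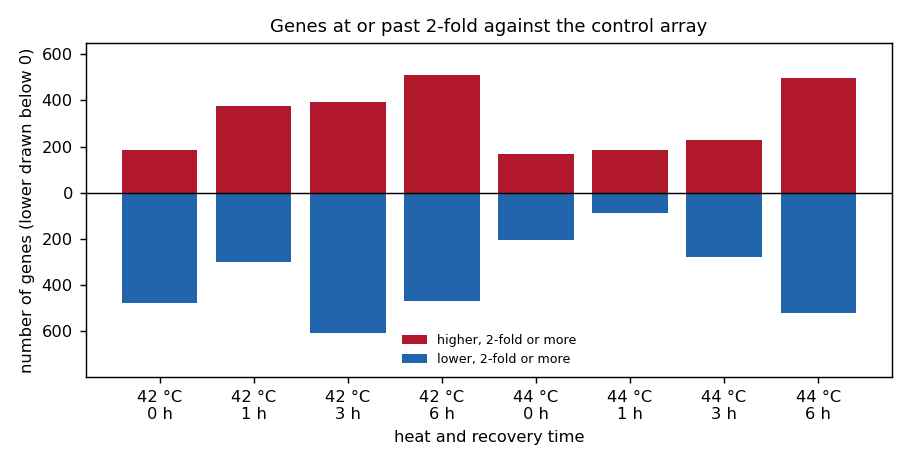
Number of genes that were higher or lower by 2-fold or more against the control array (vertical axis, lower genes drawn below 0) for each heat temperature and recovery time (horizontal axis), 1 array each. At 42 °C the number higher ran from 184 at 0 h to 512 at 6 h, and at 44 °C from 169 to 496.

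Directly after 15 min at 42 °C, transcripts of heat shock chaperones were already far above the control. HSPA6, a stress-inducible HSP70, rose 34.4-fold, from a scaled signal of 138 to 4751. BAG3, a partner of HSP70, rose 9.05-fold, the HSP40 member DNAJB1 rose 8.28-fold and SERPINH1, a collagen chaperone, rose at least 14.01-fold. The larger HSP110 member HSPH1 rose 2.67-fold and the small heat shock protein HSPB1 2.46-fold, while HSP90AA1 had a log2 fold of 0.45. In all, 14 of 31 measured chaperone genes rose and 0 fell, with a list median of 0.86 (percentile 100). That list, counted as chaperone genes throughout, also holds genes that are not chaperones, such as ZFAND2A and DEDD2. HSPA1A, HSPA1B and HSPA8 have no probe set assigned to 1 gene alone and were given no level.

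Genes of cholesterol synthesis and of the integrated stress response list were lower on the same array. INSIG1, which retains sterol regulators in the endoplasmic reticulum, fell 4.32-fold, the mevalonate pathway enzymes HMGCS1 and MVD fell 3.44-fold and 2.44-fold, and the sterol regulator SREBF1 fell at least 15.2-fold. Of 14 measured genes of cholesterol synthesis 6 fell and 0 rose (median -0.88, percentile 0). In the integrated stress response list 6 of 22 fell and 1 rose (median -0.38, percentile 0.01), among them the cystine transporter SLC7A11 (4.41-fold lower), CTH of cysteine synthesis (4.13-fold lower) and asparagine synthetase ASNS (3.31-fold lower). MYC, a growth-promoting transcription factor, fell 5.08-fold, and the receptors GPR183 and GPR65 fell 7.97-fold and 7.29-fold.

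Immediate early genes went both ways at 42 °C and 0 h: 4 of 30 rose and 8 fell (median 0.00). IER5 rose 7.31-fold, while IER2 fell 3.86-fold and JUN 2.34-fold. DUSP1, a phosphatase of MAP kinases, rose 4.75-fold by its brightest probe set, and its other probe sets gave smaller log2 folds of 0.80 to 1.14. In the inflammatory list 1 of 23 rose and 4 fell, the chemokines CCL2 and CXCL8 by 3.30-fold and 2.74-fold. Another probe set of CXCL8 had a log2 fold of -0.64. Of 29 proapoptotic genes 0 rose and 1 fell, the death receptor TNFRSF10B (2.08-fold, or a log2 fold of -0.98 with quantile normalisation), whose other probe sets had -0.36 and -0.012. Of 17 antiapoptotic genes 0 rose and 1 fell, XIAP (2.03-fold, or -0.95 in log2 with quantile normalisation), whose other probe sets ran from -1.35 to 0.83. Over all genes 184 rose and 476 fell, and with quantile normalisation 236 rose and 372 fell. The larger side turned with the floor at the 25th percentile (1709 and 1588).

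After 1 h of recovery from 42 °C the chaperone transcripts stood higher still. HSPA6 was 52.5-fold above the control, DNAJA4 37.5-fold, BAG3 17.1-fold and DNAJB1 11.0-fold, although the other probe sets of DNAJA4 ran from a log2 fold of 0.80 to 3.66. Among the 31 chaperone genes 18 rose and 0 fell (median 1.15, percentile 100). HMOX1, a heme-degrading enzyme induced by oxidants, rose 3.95-fold, and the kinase CLK1, which acts on splicing factors, rose 3.62-fold. RNA45SN5, the precursor of ribosomal RNA, rose 10.6-fold.

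Stress response genes also rose at this time. The integrated stress response list had 4 genes that rose and 1 that fell of 22 (median 0.27, percentile 99.98). Its leading members were CHAC1, which degrades glutathione (4.68-fold), PPP1R15A, which restores translation (3.75-fold), and the transcription factor ATF3 (3.30-fold). Other probe sets of ATF3 had smaller log2 folds of 0.62 and 0.69. Immediate early genes counted 9 that rose and 5 that fell of 30 (median 0.00), with KLF2 up 5.84-fold and MYC down 5.54-fold. On the proapoptotic list PMAIP1 (NOXA), a BH3-only protein, rose 3.13-fold, BMF, of the same class, rose 2.83-fold, and TNFRSF1A fell 2.33-fold, with 29 measured. Of 17 antiapoptotic genes 0 rose and 0 fell, and MCL1 had a log2 fold of -0.12 (other probe sets from -0.84 to 0.30). The cell cycle inhibitor CDKN1A rose 2.06-fold and CDKN1B fell 3.39-fold. In total 375 genes rose and 302 fell, against 286 and 356 with quantile normalisation.

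At 3 h after 42 °C HSPA6 stood 77.2-fold above the control, BAG3 29.1-fold and DNAJB1 16.6-fold. ZFAND2A, a proteasome-associated protein of the arsenite and heat response, rose 22.3-fold, and HSP90AA1 rose 2.09-fold, a call lost with quantile normalisation (log2 fold 0.43). The list counted 20 genes that rose and 0 that fell (median 1.37, percentile 100). DNAJB9 and HERPUD1, induced by unfolded proteins in the endoplasmic reticulum, rose 4.66-fold and 2.34-fold, and were the 2 of 19 genes of that list to rise, with 0 that fell (median 0.27, percentile 97.8, and 0.074 with quantile normalisation).

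Other stress genes remained above the control at 3 h. The integrated stress response list had 5 members that rose and 1 that fell (median 0.32, percentile 99.95), with SESN2, an inhibitor of growth signalling, up 3.30-fold. HMOX1 rose 6.51-fold, PMAIP1 3.45-fold and CDKN1A 3.03-fold. Proapoptotic genes counted 2 that rose and 2 that fell, and antiapoptotic genes 0 and 1, the latter PIM2 (2.10-fold, or -0.95 in log2 with quantile normalisation). The inflammatory list had 3 that rose, IL1B among them (2.66-fold), and 2 that fell, TNF (at least 4.20-fold) and CCL2 (3.67-fold). Zinc finger genes, many of which encode transcriptional repressors, mostly fell where they changed, 36 against 4 that rose of 466. CEBPA, a regulator of myeloid differentiation, fell 3.70-fold, and TFRC, the transferrin receptor, fell 2.19-fold. Altogether 392 genes rose and 610 fell, against 448 and 506 with quantile normalisation, and the larger side turned with the floor at the 25th percentile (2047 and 1818) and against the 0 h array (466 and 251).

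At 6 h after 42 °C the chaperones were still high and interferon-induced genes had joined them. DNAJA4 stood 42.7-fold above the control, HSPA6 32.8-fold and BAG3 19.0-fold, with 19 chaperone genes that rose and 0 that fell (median 1.25, percentile 100). IFIT1, IFIT2 and IFIT3, which bind foreign RNA or help those that do, rose at least 25.4-fold, 22.4-fold and 6.24-fold. They were among 5 of 23 interferon response genes that rose, with 0 that fell (median 0.15, percentile 97.8). HMOX1 reached 10.1-fold, and MS4A6A, a membrane protein of myeloid cells, 12.5-fold. Other probe sets of MS4A6A ran from a log2 fold of 0.31 to 2.96. HYAL2, a hyaluronidase, fell 11.3-fold and the chemokine CCL2 4.77-fold.

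Sterol genes were again lower at 6 h, with 2 of 14 that fell, LSS (2.44-fold) and INSIG1 (2.44-fold), and 0 that rose (median -0.53, percentile 0). The integrated stress response list had 5 genes that rose and 0 that fell, DDIT4, a repressor of growth signalling, among the former (2.59-fold). On the proapoptotic list 3 rose and 0 fell: BMF (2.25-fold), CASP8, the initiator caspase of death receptors (2.11-fold), and PMAIP1 (2.02-fold). Antiapoptotic genes counted 0 that rose and 0 that fell, with a log2 fold of -0.90 for BCL2, -0.55 for BCL2L1 and -0.15 for MCL1. Other probe sets ran from -1.68 to 0.089 for BCL2, 0.053 to 0.28 for BCL2L1 and -0.17 to 0.90 for MCL1. MYC was 2.60-fold lower. Genes of mitosis had a median of 0.24 (percentile 99.9) although none of 32 passed 2-fold. The total was 512 genes that rose and 470 that fell, and with quantile normalisation 442 and 520, which turns the larger side.

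**Figure D2:**
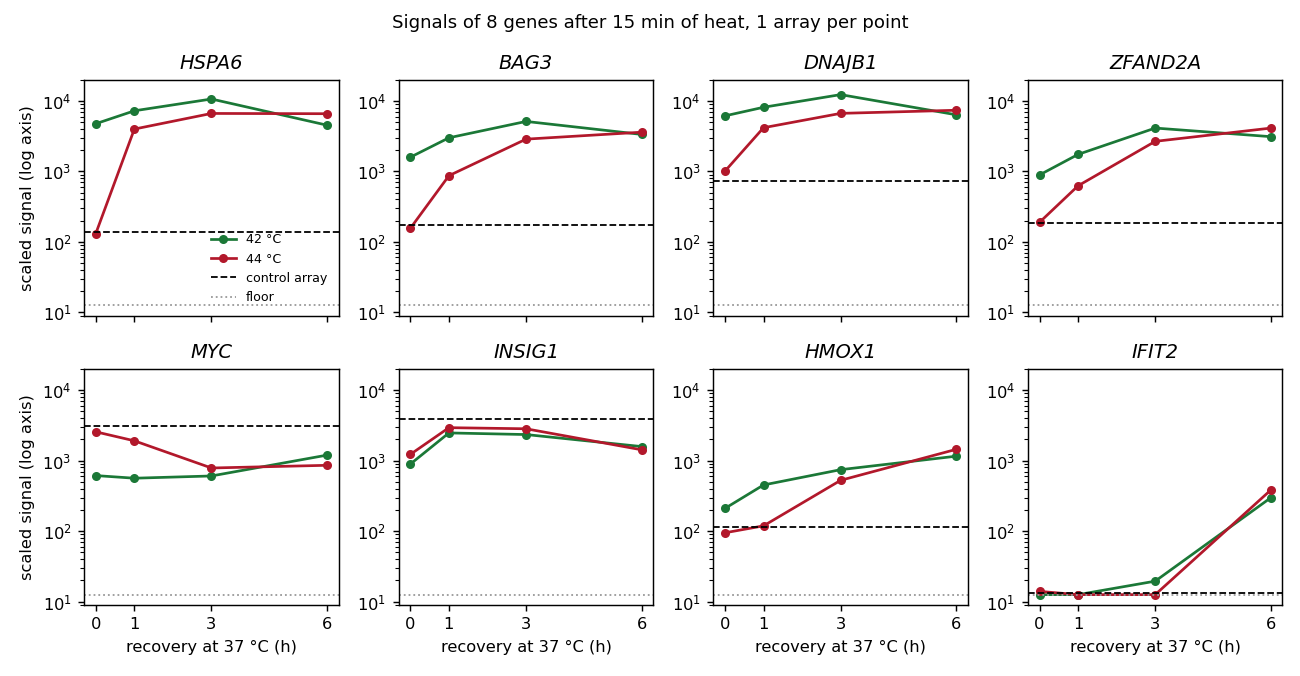
Scaled signal (log axis) of 8 genes against hours of recovery at 37 °C after 15 min at 42 °C (green) or 44 °C (red), 1 array per point, with the control array as a dashed line and the floor, to which lower signals were raised, as a dotted line. HSPA6 at 0 h was 4751 after 42 °C and 131 after 44 °C, beside 138 in the control, and at 6 h it was 4525 and 6587.

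Directly after 15 min at 44 °C the chaperone transcripts stayed close to the control. HSPA6 had a log2 fold of -0.074, BAG3 of -0.17 and DNAJB1 of 0.44. None of the 31 chaperone genes rose and 0 fell (median 0.16, percentile 99.4). Genes of sterol synthesis were lower as at 42 °C, with 5 of 14 that fell and 0 that rose (median -0.80, percentile 0), INSIG1 by 3.15-fold and MSMO1, a demethylase of the pathway, by 3.04-fold. In the integrated stress response list 5 of 22 fell and 0 rose (median -0.55, percentile 0), among them DDIT4 (4.26-fold), SLC7A11 (3.53-fold) and CTH (3.45-fold).

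At 44 °C and 0 h RGS1, a regulator of G protein signalling, fell 7.92-fold, CDKN1A 6.85-fold and JUN 3.50-fold, and immediate early genes counted 1 that rose and 4 that fell (median -0.26, percentile 0). Another probe set of RGS1 had a log2 fold of -0.66. The antiapoptotic BCL2 relative BCL2A1 fell 2.28-fold, the sole such gene of 17 to change, and of the proapoptotic genes 0 rose and 0 fell. CALR, a calcium-binding chaperone of the endoplasmic reticulum, rose 2.55-fold. ATF3 fell 2.26-fold by its brightest probe set and had a log2 fold of 0.61 by another. Over all genes 169 rose and 204 fell, against 140 and 216 with quantile normalisation, and the larger side turned with the floor at the 25th percentile (1630 and 1384). Simulated data give no measure of chance calls here, since their spread was taken from this same difference and they held more calls, 519, than were found.

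At 1 h after 44 °C the inducible chaperones had risen. HSPA6 was 28.9-fold above the control, DNAJA4 8.04-fold, DNAJB1 5.62-fold and BAG3 4.95-fold, while HSPH1 and HSPB1 had log2 folds of 0.54 and 0.45. The chaperone list counted 7 of 31 that rose and 0 that fell (median 0.23, percentile 100). Immediate early genes rose without falls, 8 against 0 of 30 (median 0.35, percentile 100), with IER5 up 5.198-fold, JUN 2.23-fold and KLF2 2.47-fold. DUSP1 rose 9.17-fold by its brightest probe set, and the median over its probe sets had the opposite sign.

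The integrated stress response list had 2 members that rose, PPP1R15A (2.42-fold) and ATF3 (2.12-fold), and 0 that fell (median 0.16, percentile 99.8). Of the sterol genes 0 rose and 0 fell (median -0.14). GPR183 fell 2.86-fold. Neither the proapoptotic list, with 0 that rose and 0 that fell, nor the antiapoptotic list, with 0 and 0, held a change of 2-fold, and PMAIP1 had a log2 fold of 0.68. The comparison counted 183 genes that rose and 90 that fell, 273 in all, fewer than the 528 called in data simulated for it without change, and 12 passed 4-fold against 14 simulated.

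By 3 h after 44 °C the chaperone response was broad. HSPA6 rose 48.1-fold, DNAJA4 27.1-fold, BAG3 16.3-fold and ZFAND2A 14.5-fold, and HSPH1 and HSPB1 now passed 2-fold with 3.05-fold and 2.21-fold. Of the 31 chaperone genes 13 rose and 0 fell (median 0.91, percentile 100). ATF3 rose 6.49-fold, CHAC1 5.79-fold and SESN2 3.25-fold, in a stress response list with 5 that rose and 0 that fell (median 0.22, percentile 99.9). Other probe sets of ATF3 ran from 0.44 to 2.05 in log2. DNAJB9 and HERPUD1 rose 4.17-fold and 2.37-fold, HMOX1 4.60-fold and CLK1 4.18-fold.

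On the immediate early list 11 rose and 4 fell (median 0.26, percentile 99.99), JUN up 3.00-fold and FOS 2.54-fold. MYC, on the same list, fell 3.97-fold and GPR183 fell 5.95-fold. PMAIP1 (2.67-fold) was the sole proapoptotic gene to rise, 0 fell, and 0 antiapoptotic genes rose and 0 fell. CDKN1A rose 2.48-fold, GADD45A, a gene of the DNA damage response, 2.04-fold and its relative GADD45B 2.79-fold. Inflammatory genes counted 3 that rose, IL1B by 2.03-fold, and 0 that fell. The count was 230 genes that rose and 279 that fell, and with quantile normalisation 270 and 216. The sum of 509 was near the 484 called in data simulated for this comparison without change, while 39 genes passed 4-fold against 14 simulated.

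At 6 h after 44 °C the chaperone list had a median of 1.47 (percentile 100), with 18 of 31 that rose and 0 that fell. DNAJA4 was 60.6-fold above the control, HSPA6 47.7-fold, ZFAND2A 22.3-fold and CRYAB, a small heat shock protein, at least 13.98-fold. IFIT1, IFIT2 and IFIT3 rose at least 29.4-fold, 28.9-fold and 5.87-fold, and the interferon list had 5 of 23 that rose and 0 that fell (median 0.27, percentile 99.99). HMOX1 rose 12.7-fold and IL7R, the interleukin 7 receptor, 9.01-fold. CCL2 fell 5.74-fold, HYAL2 5.67-fold and MYC 3.63-fold.

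Genes of apoptosis changed on both sides at 44 °C and 6 h. PMAIP1 rose 2.69-fold, the death receptor FAS 2.21-fold and CASP8 2.02-fold, the 3 proapoptotic genes of 29 to rise, with 0 that fell. On the antiapoptotic list the kinase PIM1 rose 2.63-fold and BCL2 fell 2.09-fold, just short of 2-fold with quantile normalisation, while BCL2L1 and MCL1 had log2 folds of -0.22 and 0.12. Other probe sets ran in log2 from 0.079 to 1.52 for FAS, -1.05 to -0.023 for BCL2, 0.080 to 0.36 for BCL2L1 and -0.28 to 1.11 for MCL1. CDC6, which loads the replicative helicase, rose 3.20-fold. Sterol genes had 2 that fell, INSIG1 (2.71-fold) and LSS (2.38-fold), and 0 that rose (median -0.52, percentile 0.01). In the integrated stress response list 5 rose and 1 fell (median 0.27, percentile 99.9), DDIT4 up by 2.87-fold. The sum was 496 genes that rose and 523 that fell, and with quantile normalisation 549 and 406, which turns the larger side.

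Set against each other at 0 h, the 44 °C array lay far below the 42 °C array for inducible chaperones. HSPA6 was 36.2-fold lower after 44 °C, BAG3 10.2-fold and DNAJB1 6.09-fold, and 9 chaperone genes were lower and 0 higher (median -0.54, percentile 0). The immediate early gene IER5 was 8.13-fold lower. MYC was 4.18-fold higher, GPR183 6.18-fold, GPR65 4.48-fold and the activation marker CD69 3.93-fold. CDKN1A was 5.17-fold lower and PMAIP1 2.24-fold lower, in a proapoptotic list with 1 higher and 1 lower. In total 315 genes were higher and 149 lower after 44 °C, and with quantile normalisation 215 and 210. The sum of 464 was below the 536 called in data simulated for this comparison without change, while 26 genes passed 4-fold against 19 simulated.

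At 1 h the gap in chaperones covered more genes, with 14 lower after 44 °C and 0 higher (median -0.89, percentile 0). SERPINH1 was at least 21.6-fold lower, DNAJA4 4.66-fold, BAG3 3.45-fold and HSPH1 2.75-fold, while HSPA6 differed by a log2 fold of -0.86. HMOX1 was 3.80-fold lower, CHAC1 4.13-fold and TNFAIP3, an inhibitor of NF-kB, 3.21-fold. EGR3 was 3.91-fold higher, MYC 3.40-fold and IER2 3.22-fold, with 4 immediate early genes higher and 4 lower. The numbers over all genes were 200 higher and 251 lower, against 207 and 200 with quantile normalisation, and their sum of 451 was below the 533 of simulated data without change. Past 4-fold there were 22 genes against 14 simulated.

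At 3 h fewer chaperones differed by 2-fold, 5 lower after 44 °C and 0 higher (median -0.68, percentile 0, and -0.29 with quantile normalisation). SERPINH1 was 4.65-fold lower and HSPH1 2.11-fold lower, the latter with a log2 fold of -0.53 under quantile normalisation. Immediate early genes lay higher, 5 against 0 lower, EGR3 by 3.14-fold, FOSL1 by 3.11-fold and JUN by 2.56-fold. CCL2 was 2.15-fold higher and IL7R 3.20-fold lower. In all 202 genes were higher and 193 lower, and their sum of 395 was below the 531 of simulated data without change, with 10 past 4-fold against 22 simulated.

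By 6 h none of the 31 chaperones differed by 2-fold between temperatures, with a median of -0.14 (percentile 1.5) that turned to 0.063 with quantile normalisation. HSPA6 had a log2 fold of 0.54, DNAJB1 of 0.21, BAG3 of 0.11 and HMOX1 of 0.32. JUN was 2.01-fold higher after 44 °C (0.96 in log2 with quantile normalisation), the chemokine CCL20 at least 6.23-fold higher and EGR1 3.27-fold lower. Other probe sets ran in log2 from 0.040 to 0.92 for JUN and from -0.51 to -0.46 for EGR1. Genes of mitosis had a median of -0.25 (percentile 0), with 0 higher and 0 lower by 2-fold. None of the 29 proapoptotic or 17 antiapoptotic genes differed by 2-fold. The counts were 168 genes higher and 271 lower, against 254 and 166 with quantile normalisation, and their sum of 439 was below the 533 of simulated data without change, with 10 past 4-fold against 19 simulated.

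**Figure D3:**
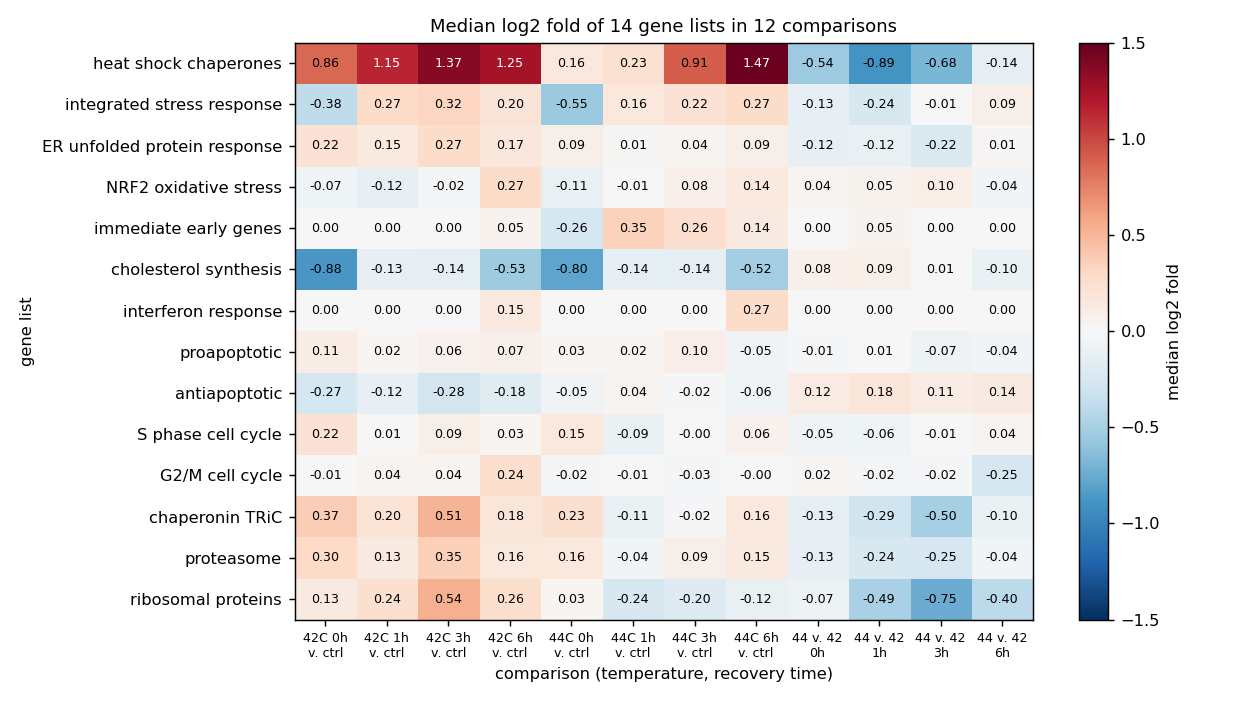
Median log2 fold (colour and printed value) of 14 gene lists (vertical) in the 12 comparisons (horizontal: each heated array against the control, then 44 °C against 42 °C at each time). Against the control, heat shock chaperones ran from 0.16 at 44 °C 0 h to 1.47 at 44 °C 6 h, and quantile normalisation turned signs for ribosomal proteins (42 °C 3 h and between temperatures at 3 h), chaperonin TRiC (between temperatures at 0 and 6 h), chaperones (between temperatures at 6 h) and some medians under 0.1 in size of 6 further lists.

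Genes changed at both temperatures overlapped at every time. Both arrays shared 145 genes that rose or fell in the same direction at 0 h, 115 at 1 h, 282 at 3 h and 476 at 6 h. At these times 40, 84, 142 and 273 of them rose, where independent lists would share 1.57, 3.47, 4.56 and 12.8. The other 105, 31, 140 and 203 fell, where independent lists would share 4.91, 1.37, 8.61 and 12.4. In 100 simulations of unchanged arrays against 1 shared control the highest number shared was 29. Their spread was a robust SD, 0.154 in log2 for the brightest genes, where the 99th percentile of early differences was 1.10. Such a spread leaves out the tails of the differences, so the shared numbers and covariances simulated here may be too low. Across genes, which are not independent replicates, Pearson's r of the log2 folds was 0.551, 0.509, 0.667 and 0.712 at 0, 1, 3 and 6 h, beside 0.5001 from the shared control alone. The covariance was 0.0714, 0.0596, 0.114 and 0.152, beside 0.0379 simulated. Part of the excess may come from the shared control, a single array. With each temperature set against its own 0 h array the 2 temperatures share no array, and simulated unchanged arrays gave an r of 0.000105 and at most 6 shared genes. On that baseline 101, 212 and 427 genes were shared at 1, 3 and 6 h, and r was 0.332, 0.416 and 0.502. Of these 94, 157 and 309 rose and 7, 55 and 118 fell, while 11, 9 and 22 others changed in opposite directions. Independent lists would share 6.08, 9.26 and 29.7 genes that rose and 0.684, 5.56 and 12.2 that fell. On either baseline, sharing at 1, 3 and 6 h cannot be told apart from change with time in culture, which no series of unheated arrays followed.

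Lists of abundant cellular machinery shifted as whole groups, by amounts that depended on the scaling. Ribosomal protein genes had medians of 0.13, 0.24, 0.54 and 0.26 against the control at 42 °C and of 0.035, -0.24, -0.20 and -0.12 at 44 °C, and with quantile normalisation all 8 lay from -0.011 to 0.0083, with the sign turned at 42 °C and 3 h. Proteasome genes (median -0.25 to 0.35 over the 12 comparisons), chaperonin TRiC (-0.50 to 0.51), nuclear genes of oxidative phosphorylation (-0.23 to 0.29), housekeeping genes (-0.25 to 0.25) and cytoplasmic tRNA synthetases (-0.24 to 0.33) likewise shifted between arrays. Quantile normalisation turned the sign of the median for housekeeping genes in all 4 comparisons at 42 °C and all 4 between temperatures, for TRiC between temperatures at 0 and 6 h and for tRNA synthetases between temperatures at 3 and 6 h. ACTB and GAPDH differed between temperatures by log2 folds of -0.87 and -0.86 at 3 h, against 0.076 and -0.058 with quantile normalisation. Of these lists proteasome, TRiC and tRNA synthetase genes never passed 2-fold, and at most 1 ribosomal gene rose and 2 fell.

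The remaining lists held few changes. At most 4 of 23 p53 targets rose and 2 fell in any of the 12 comparisons, at most 3 and 2 of 15 growth arrest genes, 2 and 3 of 20 NRF2 targets, 1 and 1 of 30 S phase genes and 0 and 1 of 32 genes of mitosis. SR proteins and CLK kinases had at most 2 and 1 of 18, heat shock factors 0 and 1 of 4 (HSF1 down by 2.07-fold at 42 °C 6 h, with another probe set at 0.40), metallothioneins 0 and 0 of 7, and small nucleolar RNA hosts 0 and 1 of 12. Histone genes had at most 3 and 3 of 45, solute carriers 8 and 10 of 316, and zinc finger genes 16 and 36 of 466.

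Among markers of cell types other than the U937 line, T cell markers had at most 1 that rose and 1 that fell of 11, B cell markers 1 and 0 of 9, epithelial and fibroblast markers 2 and 1 of 12, and erythroid markers 1 and 1 of 5, with medians of 0.00 in all 12 comparisons for T cell and for epithelial and fibroblast markers, 0.00 to 0.29 for B cell and -0.080 to 0.46 for erythroid markers. Those medians of 0.00 come from members held at the floor, and with the floor at the 25th percentile epithelial and fibroblast markers had 0.61, 0.90 and 0.85 at 42 °C (0, 3 and 6 h) and T cell markers -0.76 at 44 °C and 0 h. Members that rose included IL7R (9.01-fold at 44 °C 6 h), the hemoglobin chain HBB (at least 2.31-fold at 42 °C 1 h), the keratin KRT8 (at least 2.19-fold at 42 °C 6 h) and COL1A1, a collagen chain (at least 21.4-fold at 42 °C 6 h, with other probe sets between -0.21 and 2.68 in log2). Monocyte and macrophage markers, which this line shares, had at most 1 that rose and 2 that fell of 18.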

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

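The signals of control probe sets were looked at only after the comparisons were set, and the tests given here, of ribosomal RNA of every kind and of RNA degradation, were chosen after those signals were seen. Probe set AFFX-M27830_5_at, one of the manufacturer's controls for 28S ribosomal RNA, which was left out of the comparisons, had a deposited signal of 209.8 on the control array. At 42 °C it was 1999.7, 1907, 1049 and 335 at 0, 1, 3 and 6 h, and at 44 °C it was 19578, 20416, 11684 and 507, up to 97.3 times the control, or 89.6 times after scaling. More ribosomal RNA of every kind in the labelled material was argued against on the 44 °C arrays from 0 to 3 h and the 42 °C array at 0 h. There the 18S control probe sets reached at most 1.83 and 0.995 times the control, deposited or scaled. This explanation stays open at 42 °C at 1 and 3 h. After scaling, the 3 18S probe sets had 1.76 to 2.66 times the control at 1 h and 2.79 to 5.205 times at 3 h. Degraded messenger RNA at 44 °C was argued against by ratios of 3′ to 5′ signal for ACTB and GAPDH of at most 1.02 times the control. These ratios do not measure breakage of 28S ribosomal RNA, which was not tested and stays open. A change of 28S ribosomal RNA or of its labelling with heat, and binding of another RNA to the probes, may each account for the signal, were not tested and stay open.

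The neighbouring control probe set AFFX-M27830_M_at had a deposited signal of 5100.4 on the 44 °C array at 6 h and 959 on the control array, 5.32 times as high (4.61 after scaling), and was 2.42 times the control or more on each of the 8 heated arrays (2.99 after scaling). At 0, 1 and 3 h its scaled signals were 1965, 2033 and 2408 after 42 °C and 2673, 1831 and 1736 after 44 °C. It thus lacked the large excess at 44 °C of AFFX-M27830_5_at, on single arrays. A dimmer control probe set of the same RNA, AFFX-M27830_3_at, had scaled signals of 3.11 on the control array and 3.92 at 42 °C and 6 h, under the floor of 12.5, and of 13.4 to 41.5 on the other 7 arrays, so no fold is given for it. Of all genes, 1 lay 0.5 or more (log2) above the control at 1, 3 and 6 h after 42 °C and as far below it at the same times after 44 °C: LINC00957, a long noncoding RNA, named after its values were seen. Its log2 folds were 0.70, 0.63 and 0.72 at 42 °C and -0.58, -0.89 and -0.85 at 44 °C, and the difference between temperatures was not tested.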

How the results depend on the processing

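Of the alternatives here, 1 was chosen only after the data were seen, the floor at the 80th percentile. No paired analysis was run. The labels give no replicate numbers that pair arrays, and arrays of the same recovery time were compared by size alone. Over all alternatives 2887 folds of named genes moved by no more than the spread of the early arrays, 1420 by more and 34 turned direction. Of the list medians 1627 moved by no more than 1 SD of random lists of the same size and 485 by more, and of the numbers of changed genes 27 stayed within 1.5 times the main number and 51 did not. The heat shock chaperone medians against the control were above 0 in every comparison under quantile normalisation, the 25th and 65th percentile floors and the probe set medians, and reached down to 0.00 with the 80th percentile floor and -0.13 with the 0 h baseline. The larger side of genes that rose or fell turned in 6 of 12 comparisons with quantile normalisation, in 4, 3 and 5 of 12 with the 25th, 65th and 80th percentile floors, in 1 of 12 with the probe set medians and in 2 of 6 with the 0 h baseline. Signal over background is a limit of these arrays beside their number, and named calls were lost as the floor rose. The values that moved follow by setting, and the cause was not tested for any of them.

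With quantile normalisation 621 of 642 calls of named genes stayed past 2-fold in the same direction. The medians that moved took the following log2 values. Heat shock chaperones had 0.95 and 1.45 at 42 °C (0 and 3 h), 0.10 and 0.97 at 44 °C (0 and 3 h) and -0.77, -0.29 and 0.063 between temperatures (1, 3 and 6 h). Chaperonin TRiC genes had 0.19, 0.21 and 0.0083 at 42 °C (0, 3 and 6 h) and 0.0030, -0.12, -0.20 and 0.027 between temperatures (0, 1, 3 and 6 h). Unfolded protein response genes had 0.052 and 0.074 at 42 °C (0 and 3 h) and -0.033 between temperatures (0 h). Integrated stress response genes had -0.053 between temperatures (0 h). Immediate early genes had 0.32 and 0.32 at 44 °C (1 and 3 h). Proapoptotic genes had 0.18 at 44 °C (3 h). Antiapoptotic genes had 0.24 between temperatures (6 h). The p53 targets had 0.10 at 44 °C (3 h) and 0.12 between temperatures (3 h). G2/M genes had -0.079 at 42 °C (3 h) and -0.093 at 44 °C (3 h). S phase genes had 0.10, -0.068 and -0.073 at 42 °C (0, 1 and 3 h), -0.029 at 44 °C (1 h) and 0.053, -0.0025 and 0.055 between temperatures (0, 1 and 3 h). Inflammatory genes had 0.012 at 42 °C (1 h), 0.11 at 44 °C (6 h) and -0.032 between temperatures (6 h). NRF2 targets had 0.043 at 44 °C (1 h). Metallothioneins had 0.049 at 42 °C (0 h), 0.18 at 44 °C (1 h) and 0.00 between temperatures (0 h). Cholesterol synthesis genes had -1.01 at 42 °C (0 h). Interferon response genes had 0.34 at 44 °C (6 h) and 0.097 between temperatures (6 h). Proteasome genes had 0.17, 0.042, 0.11 and 0.066 at 42 °C (0, 1, 3 and 6 h), 0.073 at 44 °C (6 h) and -0.030, -0.073 and -0.077 between temperatures (0, 1 and 3 h). SR proteins and CLK kinases had -0.12 at 42 °C (3 h), 0.0089 at 44 °C (1 h) and 0.17 and 0.19 between temperatures (0 and 3 h). Monocyte markers had 0.0077, 0.00 and -0.37 at 42 °C (1, 3 and 6 h) and -0.034 and 0.00 between temperatures (1 and 3 h). B cell markers had 0.10 at 42 °C (1 h) and 0.20 at 44 °C (1 h). Housekeeping genes had -0.011, -0.029, -0.081 and -0.057 at 42 °C (0, 1, 3 and 6 h), -0.0081, -0.077 and -0.0033 at 44 °C (1, 3 and 6 h) and 0.059 and 0.068 between temperatures (1 and 3 h). Ribosomal proteins had 0.0083, 0.0079, -0.011 and 0.00 at 42 °C (0, 1, 3 and 6 h), 0.00, 0.00 and -0.0052 at 44 °C (1, 3 and 6 h) and -0.016, -0.0057, 0.0040 and -0.0029 between temperatures (0, 1, 3 and 6 h). Oxidative phosphorylation genes had 0.067, 0.089, 0.080 and 0.048 at 42 °C (0, 1, 3 and 6 h), 0.00, 0.021 and 0.033 at 44 °C (1, 3 and 6 h) and 0.00, -0.079, -0.029 and 0.00 between temperatures (0, 1, 3 and 6 h). The tRNA synthetases had -0.16, 0.17 and 0.12 at 42 °C (0, 1 and 3 h), 0.098 at 44 °C (1 h) and -0.077 and 0.012 between temperatures (0 and 3 h).

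With the floor at the 25th percentile 638 of 642 calls of named genes stayed. The numbers of changed genes became 3297, 3328, 3865 and 3985 at 42 °C (0, 1, 3 and 6 h), 3014, 2584, 2770 and 3315 at 44 °C (0, 1, 3 and 6 h) and 3162, 2916, 3035 and 3360 between temperatures (0, 1, 3 and 6 h). WNT5B turned to 0.45 between temperatures (6 h). Heat shock chaperones had 1.00, 1.27 and 1.62 at 42 °C (0, 1 and 3 h), 1.60 at 44 °C (6 h) and -1.03 between temperatures (1 h). Integrated stress response genes had -0.48 at 42 °C (0 h). Immediate early genes had 0.041, 0.30 and 0.29 at 42 °C (0, 1 and 6 h), 0.41, 0.47 and 0.24 at 44 °C (1, 3 and 6 h) and -0.11, 0.15 and 0.15 between temperatures (0, 1 and 6 h). The p53 targets had -0.10 at 42 °C (0 h), -0.20, -0.046 and 0.14 at 44 °C (0, 1 and 3 h) and 0.19 between temperatures (3 h). Growth arrest genes had 0.23 and 0.26 at 42 °C (1 and 6 h). Inflammatory genes had -0.27 and 0.18 at 42 °C (0 and 1 h), -0.39, -0.094, -0.16 and 0.098 at 44 °C (0, 1, 3 and 6 h) and -0.25 and -0.23 between temperatures (1 and 3 h). Interferon response genes had -0.13, 0.20 and 0.40 at 42 °C (0, 3 and 6 h), 0.064, 0.13 and 0.14 at 44 °C (0, 1 and 6 h) and 0.048 and -0.043 between temperatures (0 and 3 h). Monocyte markers had -0.089 and -0.17 at 44 °C (1 and 6 h) and 0.10 between temperatures (6 h). T cell markers had -0.055 and 0.46 at 42 °C (1 and 6 h), -0.76, -0.11 and -0.0036 at 44 °C (0, 1 and 6 h) and -0.016 and -0.34 between temperatures (0 and 6 h). B cell markers had 0.15, 0.40 and 0.45 at 42 °C (0, 1 and 3 h), 0.74, 0.22 and 0.62 at 44 °C (1, 3 and 6 h) and 0.24 and -0.42 between temperatures (1 and 3 h). Epithelial and fibroblast markers had 0.61, 0.90 and 0.85 at 42 °C (0, 3 and 6 h), 0.031 and 0.60 at 44 °C (1 and 3 h) and 0.081, 0.037 and -0.51 between temperatures (1, 3 and 6 h). Erythroid markers had -0.54 at 42 °C (3 h), 0.24 and 0.43 at 44 °C (0 and 1 h) and 0.27 between temperatures (1 h). Heat shock factors had -0.56 at 42 °C (6 h), -0.17 at 44 °C (6 h) and -0.061 and 0.27 between temperatures (0 and 6 h). Histone genes had 0.0065 and -0.047 at 42 °C (3 and 6 h), -0.010 and -0.25 at 44 °C (1 and 6 h) and 0.039, -0.024 and -0.042 between temperatures (0, 1 and 6 h). Zinc finger genes had -0.043, -0.056, -0.14 and 0.066 at 42 °C (0, 1, 3 and 6 h), -0.16 at 44 °C (3 h) and 0.087, 0.019 and -0.046 between temperatures (0, 1 and 6 h). Oxidative phosphorylation genes had -0.095 between temperatures (6 h). Solute carriers had -0.074 at 42 °C (6 h) and -0.11 at 44 °C (6 h). Small nucleolar RNA hosts had -0.46, 0.027, -0.35 and -0.15 at 42 °C (0, 1, 3 and 6 h), 0.066, -0.076 and -0.11 at 44 °C (1, 3 and 6 h) and 0.090, -0.096 and 0.067 between temperatures (0, 1 and 6 h).

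With the floor at the 65th percentile 432 of 642 calls of named genes stayed. The numbers of changed genes became 377, 347, 588 and 554 at 42 °C (0, 1, 3 and 6 h), 136, 91, 285 and 660 at 44 °C (0, 1, 3 and 6 h) and 206, 202, 145 and 129 between temperatures (0, 1, 3 and 6 h). Heat shock chaperones had 0.75 and 1.048 at 42 °C (0 and 1 h), 0.10 and 0.12 at 44 °C (0 and 1 h) and -0.078 between temperatures (6 h). Immediate early genes had 0.00 at 42 °C (6 h), -0.19, 0.20, 0.18 and 0.042 at 44 °C (0, 1, 3 and 6 h) and 0.00 between temperatures (1 h). Growth arrest genes had 0.00 at 42 °C (0 h). Inflammatory genes had 0.00, 0.00 and 0.00 at 42 °C (1, 3 and 6 h) and 0.00 and 0.00 between temperatures (3 and 6 h). Cholesterol synthesis genes had -0.35 at 42 °C (6 h). Interferon response genes had 0.00 at 42 °C (6 h) and 0.00 at 44 °C (6 h). Monocyte markers had 0.047 at 42 °C (1 h), -0.048 at 44 °C (6 h) and -0.0079 between temperatures (1 h). B cell markers had 0.00 at 42 °C (1 h) and 0.00 at 44 °C (1 h). Erythroid markers had 0.00 between temperatures (3 h). Oxidative phosphorylation genes had 0.0057 at 44 °C (3 h) and -0.039 between temperatures (6 h).

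With the floor at the 80th percentile 253 of 642 calls of named genes stayed. The numbers of changed genes became 159, 157, 259 and 232 at 42 °C (0, 1, 3 and 6 h), 49, 31, 110 and 317 at 44 °C (0, 1, 3 and 6 h) and 72, 78, 52 and 42 between temperatures (0, 1, 3 and 6 h). Heat shock chaperones had 0.50, 0.68 and 1.03 at 42 °C (0, 1 and 6 h), 0.038, 0.00, 0.44 and 0.95 at 44 °C (0, 1, 3 and 6 h) and -0.50, -0.68 and -0.019 between temperatures (0, 1 and 6 h). Integrated stress response genes had 0.085 at 42 °C (6 h), -0.30, 0.069 and 0.15 at 44 °C (0, 1 and 6 h) and 0.00, -0.13 and 0.00 between temperatures (0, 1 and 6 h). Immediate early genes had 0.00 at 42 °C (6 h), 0.00, 0.00, 0.00 and 0.00 at 44 °C (0, 1, 3 and 6 h) and 0.00 between temperatures (1 h). Proapoptotic genes had 0.00 at 42 °C (0 h) and 0.00 at 44 °C (3 h). Antiapoptotic genes had -0.035 at 42 °C (3 h). The p53 targets had 0.00 at 44 °C (0 h). Growth arrest genes had 0.00 and 0.00 at 42 °C (0 and 3 h) and 0.00 and 0.00 at 44 °C (0 and 3 h). Inflammatory genes had 0.00, 0.00 and 0.00 at 42 °C (1, 3 and 6 h) and 0.00 and 0.00 between temperatures (3 and 6 h). Cholesterol synthesis genes had -0.16 at 42 °C (6 h) and -0.044 and -0.36 at 44 °C (3 and 6 h). Interferon response genes had 0.00 at 42 °C (6 h) and 0.00 at 44 °C (6 h). Monocyte markers had 0.00, 0.00 and 0.00 at 42 °C (1, 3 and 6 h), 0.00 at 44 °C (6 h) and 0.00 and 0.00 between temperatures (1 and 3 h). B cell markers had 0.00 at 42 °C (1 h) and 0.00 at 44 °C (1 h). Erythroid markers had 0.00 between temperatures (3 h). Oxidative phosphorylation genes had 0.0057 at 44 °C (3 h) and -0.039 between temperatures (6 h).

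With the median over the probe sets of a gene 467 of 642 calls of named genes stayed, and the number of changed genes became 255 between temperatures (3 h). Directions turned, to the log2 folds given, for CLK4 -0.016 at 42 °C (0 h), ZNF230 -0.027 at 42 °C (6 h), ZNF254 -0.081 at 42 °C (6 h), ZNF71 -0.21, -0.22 and -0.22 at 44 °C (0, 1 and 6 h), ATF3 0.51 at 44 °C (0 h) and 0.13 between temperatures (0 h), DUSP1 -0.21 and -0.27 at 44 °C (1 and 6 h) and -0.21 between temperatures (6 h), ZNF335 -0.095 and -0.57 between temperatures (0 and 3 h), SLC25A16 0.70 between temperatures (3 h) and WNT5B 0.068 between temperatures (6 h). Heat shock chaperones had 1.27, 1.481 and 1.13 at 42 °C (1, 3 and 6 h), 1.31 at 44 °C (6 h) and -0.65, -1.03 and 0.092 between temperatures (0, 1 and 6 h). Chaperonin TRiC genes had 0.15 and 0.35 at 44 °C (3 and 6 h) and 0.053 between temperatures (6 h). Unfolded protein response genes had 0.30 and 0.052 at 42 °C (0 and 1 h), 0.20, 0.13 and 0.18 at 44 °C (0, 3 and 6 h) and -0.028 and 0.090 between temperatures (1 and 6 h). Integrated stress response genes had -0.11 between temperatures (1 h). Immediate early genes had 0.00 at 42 °C (6 h), -0.22, 0.26, 0.16 and 0.00 at 44 °C (0, 1, 3 and 6 h) and 0.00 and 0.049 between temperatures (1 and 3 h). Proapoptotic genes had 0.10 at 42 °C (1 h), 0.20 at 44 °C (6 h) and -0.069 between temperatures (1 h). Antiapoptotic genes had 0.14 at 42 °C (6 h), -0.057, -0.14 and 0.15 at 44 °C (1, 3 and 6 h) and 0.078, -0.035 and 0.038 between temperatures (1, 3 and 6 h). The p53 targets had 0.20 at 42 °C (6 h). Growth arrest genes had 0.00 and 0.25 at 42 °C (0 and 6 h). G2/M genes had -0.038 and 0.37 at 42 °C (3 and 6 h) and 0.11 at 44 °C (6 h). S phase genes had -0.053 and 0.054 at 44 °C (1 and 3 h). Inflammatory genes had 0.00 at 42 °C (1 h), -0.076 at 44 °C (0 h) and -0.11 and 0.00 between temperatures (3 and 6 h). NRF2 targets had -0.20, -0.077, -0.0098 and -0.033 at 44 °C (0, 1, 3 and 6 h) and -0.0042 between temperatures (3 h). Metallothioneins had 0.00 at 44 °C (1 h) and 0.035 and 0.10 between temperatures (1 and 6 h). Cholesterol synthesis genes had -1.01 at 42 °C (0 h), -0.92 at 44 °C (0 h) and -0.043 between temperatures (1 h). Interferon response genes had 0.25 at 42 °C (6 h) and 0.14 at 44 °C (6 h). Proteasome genes had 0.29 at 42 °C (3 h) and -0.18 and -0.17 between temperatures (1 and 3 h). SR proteins and CLK kinases had -0.21, 0.15 and 0.25 at 42 °C (0, 3 and 6 h), 0.043 at 44 °C (1 h) and 0.15, -0.099 and -0.10 between temperatures (0, 3 and 6 h). Monocyte markers had -0.20 at 42 °C (6 h) and -0.021 between temperatures (1 h). B cell markers had 0.00 at 42 °C (1 h) and 0.00 at 44 °C (1 h). Erythroid markers had 0.00 between temperatures (3 h). Housekeeping genes had 0.059 at 42 °C (1 h). Heat shock factors had 0.13 at 44 °C (0 h). Ribosomal proteins had 0.077 and -0.21 at 44 °C (0 and 1 h) and -0.45 and -0.63 between temperatures (1 and 3 h). Oxidative phosphorylation genes had 0.21 and 0.079 at 42 °C (3 and 6 h), -0.047 and 0.056 at 44 °C (1 and 6 h) and -0.060, -0.16, -0.14 and -0.012 between temperatures (0, 1, 3 and 6 h). The tRNA synthetases had 0.22 at 42 °C (3 h), -0.12 at 44 °C (0 h) and -0.077 and -0.056 between temperatures (0 and 3 h).

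With the 0 h array of the same temperature as baseline 218 of 355 calls stayed, the numbers of changed genes became 452 and 831 at 44 °C (1 and 3 h), and the correlation of folds between temperatures became 0.332, 0.416 and 0.502 at 1, 3 and 6 h. This alternative measures change since the end of heating. Directions turned, to the log2 folds given, for GPR65 0.33 at 42 °C (1 h), RGS1 0.54 at 42 °C (1 h), TNFRSF12A 0.031 at 42 °C (1 h), GADD45B -0.0050 and -0.13 at 42 °C (1 and 3 h), SLC34A3 -0.75 at 42 °C (1 h), PLK3 0.093 at 42 °C (3 h), HSPA6 -0.070 at 42 °C (6 h), PPP1R15A -0.28 at 42 °C (6 h), IER5 -0.13 at 42 °C (6 h), MYC 0.97 at 42 °C (6 h), TNFAIP3 -0.12 at 42 °C (6 h), INSIG1 0.83 at 42 °C (6 h) and 0.22 at 44 °C (6 h), MICOS10P1 -0.070 at 44 °C (1 h), a small nucleolar RNA 0.18 at 44 °C (1 h) and ZNF71 -0.46 and -0.18 at 44 °C (1 and 6 h). Heat shock chaperones had 0.26, 0.67 and 0.36 at 42 °C (1, 3 and 6 h) and -0.13, 0.53 and 0.97 at 44 °C (1, 3 and 6 h). Chaperonin TRiC genes had -0.16, 0.19 and -0.11 at 42 °C (1, 3 and 6 h) and -0.33 and -0.15 at 44 °C (1 and 3 h). Unfolded protein response genes had -0.089, 0.098 and -0.15 at 42 °C (1, 3 and 6 h) and -0.17 and -0.16 at 44 °C (1 and 3 h). Integrated stress response genes had 0.83, 0.86 and 0.72 at 42 °C (1, 3 and 6 h) and 0.66, 0.85 and 0.84 at 44 °C (1, 3 and 6 h). Immediate early genes had 0.47, 0.24 and 0.34 at 42 °C (1, 3 and 6 h) and 0.49 and 0.35 at 44 °C (1 and 6 h). Proapoptotic genes had -0.081 at 42 °C (1 h). Antiapoptotic genes had 0.28, 0.047 and 0.073 at 42 °C (1, 3 and 6 h) and 0.075 at 44 °C (3 h). The p53 targets had 0.11 and 0.20 at 42 °C (1 and 6 h) and 0.055, 0.11 and 0.19 at 44 °C (1, 3 and 6 h). Growth arrest genes had 0.15 and 0.00 at 42 °C (1 and 3 h) and 0.20, 0.36 and 0.26 at 44 °C (1, 3 and 6 h). G2/M genes had 0.33 at 42 °C (6 h) and 0.053, 0.11 and 0.10 at 44 °C (1, 3 and 6 h). S phase genes had -0.25, -0.13 and -0.093 at 42 °C (1, 3 and 6 h) and -0.27, -0.17 and -0.078 at 44 °C (1, 3 and 6 h). Inflammatory genes had 0.26 and 0.26 at 42 °C (1 and 6 h) and 0.12 at 44 °C (6 h). NRF2 targets had 0.13, 0.23 and 0.38 at 42 °C (1, 3 and 6 h) and 0.16, 0.28 and 0.31 at 44 °C (1, 3 and 6 h). Metallothioneins had -0.24, -0.24 and -0.26 at 42 °C (1, 3 and 6 h) and -0.093, -0.10 and -0.018 at 44 °C (1, 3 and 6 h). Cholesterol synthesis genes had 0.68, 0.74 and 0.54 at 42 °C (1, 3 and 6 h) and 0.68, 0.58 and 0.29 at 44 °C (1, 3 and 6 h). Interferon response genes had 0.30 at 42 °C (6 h) and 0.41 at 44 °C (6 h). Proteasome genes had -0.18, 0.069 and -0.13 at 42 °C (1, 3 and 6 h) and -0.23, -0.11 and -0.080 at 44 °C (1, 3 and 6 h). SR proteins and CLK kinases had -0.057 and -0.100 at 44 °C (3 and 6 h). Monocyte markers had 0.00, 0.00 and -0.11 at 42 °C (1, 3 and 6 h) and 0.00 at 44 °C (6 h). B cell markers had 0.12 at 42 °C (1 h). Erythroid markers had -0.33 at 44 °C (1 h). Housekeeping genes had -0.034 and 0.086 at 42 °C (1 and 3 h) and -0.30 at 44 °C (3 h). Heat shock factors had -0.057, -0.040 and -0.23 at 42 °C (1, 3 and 6 h) and -0.16, -0.22 and -0.15 at 44 °C (1, 3 and 6 h). Ribosomal proteins had 0.10, 0.40 and 0.13 at 42 °C (1, 3 and 6 h) and -0.29 and -0.25 at 44 °C (1 and 3 h). Oxidative phosphorylation genes had -0.033, 0.074 and -0.063 at 42 °C (1, 3 and 6 h) and -0.19, -0.070 and -0.012 at 44 °C (1, 3 and 6 h). The tRNA synthetases had 0.44 at 42 °C (3 h) and 0.26, 0.41 and 0.31 at 44 °C (1, 3 and 6 h).

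With the threshold taken from the spread of the early arrays the numbers of changed genes became 216, 238, 371 and 346 at 42 °C (0, 1, 3 and 6 h), 113, 77, 162 and 357 at 44 °C (0, 1, 3 and 6 h) and 151, 155, 112 and 154 between temperatures (0, 1, 3 and 6 h). That spread includes the early response to heat.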

Other observations

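Tests chosen only after the result was seen were those of unheated RNA, of a later onset and of a wider interferon response. Other genes also rose after heat, with values at times when a gene was not among the largest changes added after they were seen. RGS2, a regulator of G protein signalling, rose 7.21-fold, 12.6-fold and 13.1-fold at 0, 1 and 3 h after 42 °C, and 6.26-fold and 13.8-fold at 1 and 3 h after 44 °C, with a log2 fold of 0.16 at 0 h. RNA45SN5, the ribosomal RNA precursor, rose 2.16-fold, 10.6-fold, 9.11-fold and 5.99-fold at 42 °C. At 44 °C it fell 2.04-fold at 0 h and rose 3.48-fold, 9.62-fold and 6.72-fold later. IL7R rose 2.83-fold, 7.37-fold and 7.17-fold from 1 to 6 h after 42 °C and 2.31-fold and 9.01-fold at 3 and 6 h after 44 °C. CLK1 rose 2.32-fold, 3.62-fold and 3.97-fold at 0, 1 and 3 h after 42 °C, and 4.18-fold at 3 h after 44 °C. Neither CLK1 nor IL7R passed 2-fold at the times not listed for it here.

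The chaperone list was near the control on the 44 °C array at 0 h, when it was already high at 42 °C. An exchange of the 2 arrays at 0 h was argued against, since each lay closer to the 1 h array of its own temperature, with root mean square log2 differences of 0.358 and 0.360 against 0.389 and 0.425 crossed, a ratio of sums of 0.883. A later onset of the chaperone response after 44 °C is a hypothesis that stays open: its test was set after the course was seen, and the list median at 6 h lay 0.22 above that at 42 °C, while the gene-by-gene median of the difference was -0.14 (0.063 with quantile normalisation), which leaves its direction unsettled. From 0 to 1 h at 44 °C the scaled signal of HSPA6 went from 131 to 3988, BAG3 from 156 to 869 and DNAJB1 from 1008 to 4168. HSPH1, on the same list, moved less, from 1812 to 2127. Over that time the list median went from 0.16 to 0.23, but from 0.038 to 0.00 with the 80th percentile floor. It was -0.13 at 1 h against the 0 h array. RNA of unheated cells on that array had values against it without being excluded, and a difference between single cultures may also account for the pattern: AFFX-M27830_5_at had 93.3 times its control signal there, from a cause that is open, while the fall of 5 of 14 cholesterol genes (median -0.80) and the 145 calls shared with 42 °C at 0 h, against at most 29 simulated, rest on the same single control array. The 29 may also be too low, since the simulated spread leaves out the tails of the differences.

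Ribosomal protein medians differed between arrays, with -0.75 for 44 °C against 42 °C at 3 h. Compression of bright signals under a single scaling factor predicts that other genes of the same brightness shift alike. The 20 nearest genes in mean signal per member had a median of -0.71, and the median over members of each member's difference from its neighbours was 0.00157. The shift may therefore belong to bright signals rather than to ribosomal genes, and no biological explanation was tested.

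The rise of IFIT genes at 6 h may belong to a wider interferon response, as a hypothesis. The other 13 members of that list off the floor had medians of 0.33 at 42 °C and 0.39 at 44 °C, between the bounds set for and against it, so the test left it undecided. At each temperature 1 of them rose: OAS2 at 42 °C (log2 fold 1.15) and OASL at 44 °C (1.03).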
